A study of Mus musculus with 50 samples.

How the data were processed

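Poly(A) RNA (16 libraries), total RNA (12) and LiRibo-seq footprints (14, of which 2 are ESC) were analysed, 42 of the 50 samples of the series in 21 groups of 2. The 8 ATAC-seq samples, which concern CHX-treated zygotes and Smarcd2 knockdown embryos, were not analysed here, so the report holds no value for the Smarcd2 knockdown. The submitters' processing notes list Trimmomatic 0.39, STAR 2.7.8a, RSEM 1.3.1 and GRCm38 for the RNA libraries, and cutadapt 2.10, Bowtie2 2.4.2, STAR and RSEM for LiRibo-seq. They do not state the role or settings of each tool. Each deposited file holds the output of RSEM for 1 library. Per the file headers its expected count is the number of reads or fragments RSEM assigned to a gene, not normalised, and its TPM is scaled by transcript length and library total by the authors' run of RSEM. The TPM values were not used here. The RNA files list 55385 genes, 55144 with a symbol, and the LiRibo-seq files 21856, 21816 with a symbol. Low-input RNA-seq and LiRibo-seq reads carry no molecular identifiers that were used here, so counts are not independent molecules.

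Expected counts were rounded to whole numbers and fitted in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1, data.table version 1.17.8): TMM scaling, genes kept by filterByExpr over the groups of the fit, robust quasi-likelihood fit and F test, and a call at Benjamini-Hochberg adjusted p under 0.05. Poly(A) libraries made 1 fit (20445 genes, 8 residual degrees of freedom, common biological coefficient of variation 0.285). Total RNA made another (18390 genes, 6 degrees of freedom, 0.234) and embryo LiRibo-seq another (8090 genes, 6 degrees of freedom, 0.246). Translation efficiency was tested as the interaction of assay and stage in 1 fit of 24 libraries (8036 genes, 12 degrees of freedom, 0.168), and poly(A) against total RNA as the interaction in 1 fit of 8 libraries (15571 genes, 4 degrees of freedom, 0.189). CPM of a group come from the fit in which they are reported, except that levels beside the late genes, those of Igsf6 and the later ones of Dtna, the Zfp42 and other stem cell levels and the shares of footprints are scaled by library totals alone. With 2 libraries per group the spread is shared over all groups of a fit.

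Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated for each list. Counts adjusted over the list alone repeat the adjustment over its members only. Overlaps between calls were tested with Fisher's exact test among the genes tested in both. The adjusted p threshold, the lists, the comparisons, the naming rule and most alternatives were fixed before the data were examined. The naming rule took, in the 4 poly(A) comparisons and the first 2 steps of translation efficiency, the 8 genes with the highest and the 8 with the lowest fold change, and in other comparisons 3 and 3. They had to be called, reach a mean of 10 CPM in the higher group, have a gene symbol that is not a predicted or clone name, and have all libraries of one group above all of the other. The last condition was not required for translation efficiency or for poly(A) against total RNA. Up to 4 members with the smallest adjusted p were named for each list described, and Ccnt2 and Smarcd2 in every group. Some genes that the rule selects are not reported here.

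Alternatives tried were DESeq2 1.42.0, RLE factors, library totals alone, no filter on low counts, a replicate block, leaving out each library in turn and, for overlaps, a minimum 2-fold change. After the data had been seen, 4 more were added: fits of the compared groups alone, the LiRibo-seq test with the spread of the total RNA libraries, and fits without the MII or without the 2-cell LiRibo-seq and total RNA libraries. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other groups. The tests were also tested on simulated data of the change from MII to 1-cell in each assay, with 200 changed genes in 5 runs each, after a first version with 1 run had been seen. At a true 4-fold change 97.2% of these genes were called in poly(A) RNA, 96.6% in total RNA, 54% in LiRibo-seq, 70.2% in translation efficiency and 95.8% in poly(A) against total RNA, and at 2-fold 41%, 65.6%, 10%, 17.4% and 28.6%. The other comparisons were not simulated. False calls made up 2.7% to 8.4% of all calls. The simulation kept every other gene at the same mean in all groups and raised as many genes as it lowered. It therefore could not show false calls that come from library scaling. Library checks and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.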

Results

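The data comprised 42 sequencing libraries in 21 groups of 2 40 of them from B6D2F1/J mouse oocytes and preimplantation embryos and 2, of LiRibo-seq, from embryonic stem cells (ESC). Poly(A) RNA was sequenced in 16 libraries: MII oocytes (eggs arrested in meiotic metaphase II), 1-cell embryos, zygotes treated with 20 µg/ml cycloheximide (CHX, which blocks protein synthesis) or its DMSO control, zygotes treated with 20 µg/ml α-amanitin (AMA, which blocks RNA polymerase II) or their own control, and 2-cell embryos grown from oocytes injected with 5 µM siRNA against Ccnt2 or control siRNA. Total RNA was sequenced in 12 libraries and ribosome footprints in 12 libraries of the same 6 stages. These were the MII oocyte and embryos collected 12 hours (1-cell), 30 hours (2-cell), 48 hours (4-cell), 72 hours (morula) and 96 hours (blastocyst) post fertilisation. LiRibo-seq is a low-input form of ribosome profiling, which sequences mRNA pieces held by ribosomes, here from 100 to 250 oocytes or embryos per library. Depth, as counts on genes x 1e6, was 8.00 to 29.1 in poly(A) libraries and 12.5 to 19.9 in total RNA libraries. It was 0.088 to 1.78 in the embryo LiRibo-seq libraries, which detected 4107 to 9487 genes, and 4.95 to 5.46 in ESC.

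Levels are counts per library size scaled by the TMM factors of the fit (CPM), or by library totals alone where stated, given as mean ± SD with n = 2 libraries in every group, and folds come from edgeR. Every p is adjusted by the Benjamini-Hochberg method unless stated otherwise, and it measures only the spread between these libraries. The LiRibo-seq pairs of the 5 embryo stages differed by little more than counting error, with a chi-squared per degree of freedom of 1.11 to 1.28. That value was 25.04 for the MII LiRibo-seq pair, 5.53 to 43.1 for total RNA and 8.06 to 106 for poly(A) RNA. The p-values of all LiRibo-seq stages rest on a spread shared between these narrow embryo pairs and the wide MII pair. Intervals and lower bounds on folds cover counting error only. Among the genes named by the rule, the uncertainty of read assignment, as the posterior SD in percent of the counts, was 44.3% for Hist1h2ao, 20.9% for mt-Co3, 16.3% for Hist1h4m and 10.4% to 14.5% for Cphx3, Srp54b, mt-Nd4l and AV320801. A bound is set against a floor of 3 counts over a group that has none, and beside translation efficiency it is a bound on the change of footprints alone, not on the efficiency.

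**Figure D1:**
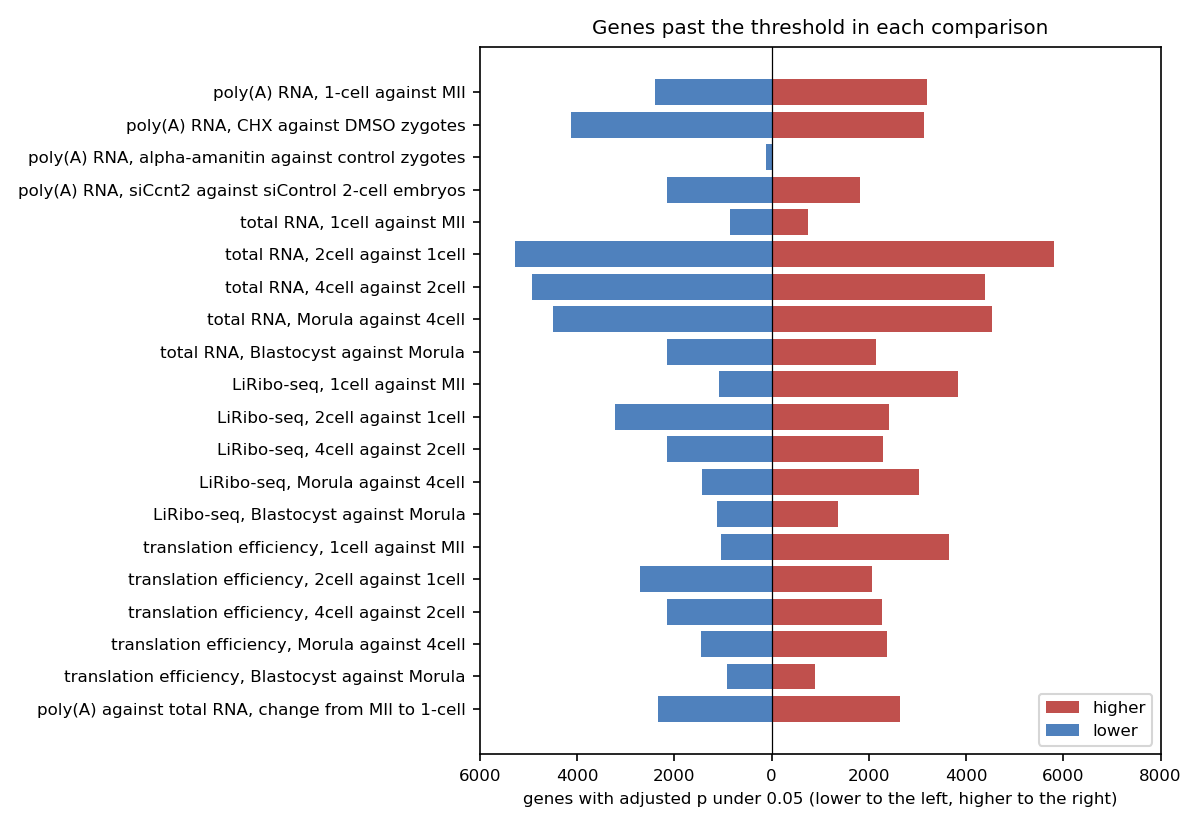
Bars give the number of genes called higher (above 0) and lower (below 0) at adjusted p under 0.05 in each of the 20 comparisons, by edgeR. The change from 1-cell to 2-cell in total RNA has the most calls, 5812 higher and 5277 lower, and α-amanitin the fewest, 1 higher and 118 lower.

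The poly(A) libraries of MII oocytes and 1-cell embryos were compared to ask which polyadenylated transcripts change after fertilisation. The transcript of Mos (ENSMUSG00000078365.5), the kinase that holds the egg in metaphase, went from 949 ± 67.3 to 14.2 ± 0.7 CPM, a 66.6-fold drop (log2 change -6.06, SE 0.96, adjusted p = 0.0013). Bub1b (ENSMUSG00000040084.9), a spindle checkpoint kinase, fell 33.5-fold from 1720 ± 178 to 51.3 ± 7.9 CPM (adjusted p = 1.3e-07). Gdf9, an oocyte growth factor, fell 14.3-fold to 331 ± 7.44 CPM and H1foo, the oocyte linker histone, 18-fold to 509 ± 31.1 CPM. On the other side the metallothioneins Mt2 and Mt1, which bind heavy metals, rose 42.2-fold to 11 ± 2.02 CPM and 34.2-fold to 11.1 ± 1.48 CPM, and the carbonic anhydrase Car9 rose 25.8-fold to 81.7 ± 2.09 CPM. The histone gene Hist2h2aa2 had no counts at MII and 22.5 ± 4.61 CPM at 1-cell, at least 236-fold higher by counting error alone. The SE of its log2 change was wide, at 2.04. Of the other genes named by the rule, Vaultrc5, Sgta, Pgpep1 and Agpat2 rose 20.8- to 30.6-fold, and Il1rap, Btg1, Efna1, Taldo1, March7 and Snx14 fell 26.7- to 41-fold.

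Among the lists fixed beforehand, genes known for a brief peak at the 2-cell stage already rose at 1-cell: 19 of 29 were higher and 0 lower (21 higher adjusted over the list alone). Arg2 rose 15.6-fold to 459 ± 39.7 CPM and Zscan4d 6.45-fold to 24.9 ± 3.8 CPM. The camera test gave adjusted p = 6.9e-11, and adjusted p = 0.0341 with an estimated correlation. Ribosomal protein genes were higher for 39 of 88 and lower for 11 (39 and 14 adjusted over the list alone). Rps9 rose 11.6-fold to 17.2 ± 1.16 CPM, and the list had adjusted p = 0.0015 but adjusted p = 0.543 with an estimated correlation. Nuclear genes of oxidative phosphorylation were higher for 29 of 80 and lower for 10 (31 and 12 adjusted over the list alone). Atp5j2 rose 6.96-fold (list adjusted p = 0.015, but adjusted p = 0.543 with an estimated correlation). Replication-dependent histone genes were higher for 10 of 39 and lower for 1 (12 and 1 adjusted over the list alone). Hist1h2bk rose 16-fold (list adjusted p = 0.013, but adjusted p = 0.339 with an estimated correlation).

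Other lists were lower at 1-cell. RNA polymerase II and general factors had 17 of 44 lower and 5 higher (21 and 6 adjusted over the list alone; list adjusted p = 2.0e-04, but adjusted p = 0.117 with an estimated correlation). Splicing genes were lower for 16 of 47 and higher for 9 (21 and 10 adjusted over the list alone; list adjusted p = 0.020, but adjusted p = 0.307 with an estimated correlation). DNA methylation and maternal chromatin genes were lower for 9 of 33 and higher for 3 (10 and 4 adjusted over the list alone; list adjusted p = 0.025, but adjusted p = 0.202 with an estimated correlation). Library totals turned the medians of the last 2 lists to 0.02 and 0.06. The maternal mRNA decay list, made of deadenylase, decapping and uridylation factors, had 13 of 28 lower and 3 higher (14 and 3 adjusted over the list alone). Dcp1a fell 3.87-fold to 200 ± 12.1 CPM (list adjusted p = 0.0012, but adjusted p = 0.0897 with an estimated correlation). Of the oocyte and maternal effect list 10 of 29 fell and 3 rose, the same counts adjusted over the list alone, and Zar1l rose 3.62-fold (list adjusted p = 0.0045, but adjusted p = 0.530 with an estimated correlation). M phase genes fell for 12 of 29 and rose for 6 (13 and 6 adjusted over the list alone). Espl1, the separase, fell 3.1-fold and Cdc25b rose 5.94-fold (list adjusted p = 0.033, but adjusted p = 0.339 with an estimated correlation).

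In all, edgeR called 3197 of 20445 genes higher and 2409 lower. Scaling by library totals moved the median change of all genes from 0.21 to 0.66 and the calls to 4812 higher and 951 lower, turned the median of the oocyte list from -0.24 to 0.21 and left Edc4, lower 2.18-fold, at adjusted p = 0.071. Calls dropped from 5606 to 3482 without MII replicate 2, to 3615 without 1-cell replicate 1 and to 3137 without 1-cell replicate 2. Without these same libraries 8, 8 and 6 decay genes and 6, 6 and 5 M phase genes were lower, and 6 and 4 oocyte genes without MII replicate 2 and 1-cell replicate 2. RNA polymerase II genes lower were 10, 9 and 7 and splicing genes 9, 10 and 8 without the same 3 libraries. Without MII replicate 1, 25 ribosomal protein genes were higher. A fit of these 4 libraries alone had 19 histone genes higher.

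Zygotes with CHX were compared with DMSO zygotes to ask which transcripts of the zygote need new protein. The transcript of H1foo (ENSMUSG00000042279.13) was at 19200 ± 562 CPM with CHX against 460 ± 108, 41.6-fold higher (log2 change 5.38, SE 0.31, adjusted p = 4.0e-09), and Mos was 28.9-fold higher with a wide spread, 514 ± 605 against 17.6 ± 6.04 CPM (adjusted p = 0.0022). Efna1, Taldo1 and Btg1, which fell from MII to 1-cell, were 28.5- to 36.3-fold higher, and Abhd17a, C1qtnf12 and Rnf215 39.5- to 45.8-fold. Lower with CHX were H3f3c, a histone H3 gene, 65.4-fold down to 1.34 ± 1.9 CPM, the deubiquitinase gene Usp17lc, 44.6-fold down to 0.273 ± 0.386 CPM, and Chchd2, a mitochondrial protein, 28.1-fold down from 165 ± 1.81 to 5.94 ± 0.982 CPM. Slc10a6, Sipa1, Tpi1, Sar1b and Sec61g fell 23.8- to 38-fold.

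Nuclear genes of oxidative phosphorylation were lower with CHX for 58 of 80 and higher for 7 (59 and 8 adjusted over the list alone). Ndufb5 fell 12.5-fold to 4.48 ± 0.768 CPM (list adjusted p = 3.0e-12, but adjusted p = 0.141 with an estimated correlation). Ribosomal protein genes were lower for 54 of 88 and higher for 7 (57 and 7 adjusted over the list alone). Rpl19 fell 7.09-fold (list adjusted p = 1.6e-07, but adjusted p = 0.358 with an estimated correlation). Of the 2-cell transient list 14 of 29 fell and 0 rose (15 and 0 adjusted over the list alone). Arg2 fell 17.4-fold to 27.8 ± 5.52 CPM, and Zfp352 fell to no counts, at least 34.2-fold (list adjusted p = 2.4e-04, but adjusted p = 0.141 with an estimated correlation). The mitochondrially encoded proteins rose instead, 12 of 13 higher (13 adjusted over the list alone). mt-Co2 rose 2.72-fold to 6740 ± 392 CPM (list adjusted p = 1.8e-05, but adjusted p = 0.358 with an estimated correlation). M phase genes were higher for 13 of 29 and lower for 6 (15 and 6 adjusted over the list alone), among them Bub1b 23.1-fold up and the chromosomal passenger kinase Aurkb 6.25-fold down (list adjusted p = 0.0011, but adjusted p = 0.141 with an estimated correlation).

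The edgeR test called 3140 genes higher and 4131 lower with CHX. The CHX libraries detected 18043 and 16966 genes against 23805 and 21841 with DMSO. Library totals moved the median change from -0.36 to -0.96 and the calls to 1497 higher and 6356 lower. Without DMSO replicate 1 4 mitochondrial genes were called higher, and fitted without the other groups Bub1b (adjusted p = 0.064), Mos (adjusted p = 0.20) and H3f3c (adjusted p = 0.082) lost their calls.

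AMA zygotes were compared with their controls to ask which transcripts RNA polymerase II makes in the zygote. The transcripts called lower were few and sharply lower. Gadd45g (ENSMUSG00000021453.2), a stress-response gene, went from 11.3 ± 0.996 to 0.197 ± 0.143 CPM, 56-fold lower (log2 change -5.81, SE 0.61, adjusted p = 6.3e-05). Usp17lc (ENSMUSG00000058976.4) fell 16.4-fold from 14 ± 0.781 CPM and the transcriptional inhibitor Id2 4.59-fold from 17.2 ± 2 CPM. Of the 2-cell transient list 9 of 29 fell and 0 rose (11 and 0 adjusted over the list alone). Usp17ld fell 33.2-fold, Usp17la 41.9-fold and Zfp352 41-fold. The call held with adjusted p = 7.0e-04 with an estimated correlation (1.3e-32 with the preset one). Ribosomal protein genes fell for 4 of 88, namely Rps19, Rpl9, Rpl13 and Rpl26, by 2.31- to 4.77-fold (5 adjusted over the list alone), and none rose (list adjusted p = 1.6e-06, but adjusted p = 0.537 with an estimated correlation). Among the immediate early genes Dusp6 fell 6.53-fold to 0.197 ± 0.143 CPM, 1 of 20 (4 adjusted over the list alone), while Myc was at 2 counts against 27 (adjusted p = 0.14), and the list had adjusted p = 7.8e-04, but adjusted p = 0.228 with an estimated correlation. The sperm transcripts had 0 of 10 called, also adjusted over the list alone, with a list adjusted p = 0.049 and adjusted p = 0.228 with an estimated correlation.

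With AMA edgeR called 1 gene higher and 118 lower, 961 genes had an unadjusted p under 0.05, and DESeq2 called 5 and 169. No filter on low counts gave 9 higher and 287 lower. The AMA libraries detected 22914 and 22880 genes against 27281 and 26610 in their controls, so the calls may miss genes that fell. The 1 higher gene, Gm10163 (ENSMUSG00000066443.5), a predicted gene chosen after its values were seen, had no counts in both control libraries and 19 ± 2.98 CPM with AMA. That is at least 383-fold higher by counting error alone, but the uncertainty of its read assignment was 23.1% of its counts. It was also at 15.4 ± 21.8 CPM in the MII total RNA pair, present in 1 library alone. Calls dropped from 119 to 57 without control replicate 1, to 47 without AMA replicate 1 and to 36 without AMA replicate 2, and the 2-cell list had 5 genes lower without control replicate 2 or AMA replicate 2. A replicate block left Rpl13 at adjusted p = 0.068, Rpl9 at 0.065, Rpl26 at 0.11 and Dusp6 at 0.056. The 4 ribosomal protein genes became 0 without control replicate 1 or AMA replicate 1, 2 without control replicate 2 and 1 without AMA replicate 2, which also left Id2 at adjusted p = 0.057. Dusp6 lost its call without control replicate 1 or either AMA library.

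The knockdown of Ccnt2, a cyclin of the elongation factor P-TEFb, was compared with control siRNA to ask what the maternal supply of this cyclin does for 2-cell transcription. Ccnt2 (ENSMUSG00000026349.14) itself was 3.13-fold lower, 17.5 ± 0.667 against 54.9 ± 10.9 CPM (log2 change -1.65, SE 0.20, adjusted p = 1.7e-04), and its relative Ccnt1 was 1.72-fold lower (adjusted p = 0.014). The homeobox gene Obox3 fell 4-fold from 532 ± 116 to 133 ± 30 CPM and Obox6 2.65-fold from 547 ± 124 CPM. Vmn2r94, AC125544.1 and Kctd12 fell 13.3- to 16.9-fold, and Glod5, Mcts1, Pramel3 and Olfr815 6.94- to 8.94-fold. Higher were Nrsn1, 5.69-fold to 12.3 ± 3.43 CPM, the kinase Cdk20, 4.1-fold to 110 ± 64.1 CPM, and Mapk1ip1, Dgcr6, Llgl1, Scin, Fam187b and Csf1, 3.95- to 4.27-fold.

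Ribosomal protein genes fell for 61 of 88 and none rose (70 adjusted over the list alone). Rps23 fell 3.17-fold to 43.1 ± 4.25 CPM (list adjusted p = 1.6e-22, but adjusted p = 0.0525 with an estimated correlation). Ribosome biogenesis genes fell for 26 of 41 and none rose (29 adjusted over the list alone). Nop58, a box C/D RNA-protein, fell 3.28-fold to 98.2 ± 39.2 CPM, and the list call held (adjusted p = 0.034 with an estimated correlation). Splicing genes fell for 20 of 47 and rose for 1 (23 and 1 adjusted over the list alone). Sf3b6 fell 3.36-fold (list adjusted p = 5.0e-06, but adjusted p = 0.0505 with an estimated correlation). Of the RNA polymerase II and general factors 17 of 44 fell and 1 rose (19 and 1 adjusted over the list alone). Polr2k fell 4.69-fold (list adjusted p = 1.9e-05, but adjusted p = 0.0525 with an estimated correlation). The 2-cell transient list had 9 of 29 lower and 0 higher (10 and 0 adjusted over the list alone; list adjusted p = 1.2e-04, but adjusted p = 0.0525 with an estimated correlation). Oocyte genes were higher for 11 of 29 and lower for 1 (16 and 3 adjusted over the list alone). The nucleoplasmin Npm2 rose 2.53-fold to 180 ± 72 CPM (list adjusted p = 6.3e-05, but adjusted p = 0.339 with an estimated correlation).

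The knockdown test called 1819 genes higher and 2143 lower with edgeR and 1592 and 2968 with DESeq2, where the median change moved from -0.02 to -0.17. Library totals turned the balance, with 2026 higher, 1660 lower and a median of 0.08, as did no filter on low counts, with 2225 and 2069. Fitted on the 4 knockdown libraries alone it called 120, and it called 2351 without siCcnt2 replicate 1 and 1820 without siControl replicate 1, which also ended the calls of Llgl1, Fam187b and Pramel3 and left 3 and 5 oocyte genes higher, against 17 without siCcnt2 replicate 2. Ribosomal protein genes went from 61 lower to 35 and 31 without the same 2 libraries, and without siControl replicate 1 alone 17 biogenesis, 8 splicing and 11 RNA polymerase II genes were lower. In the fit of the 4 libraries alone the 120 calls were 4 higher and 116 lower, with a median change of 0.07. In that fit 2 ribosomal protein genes and 2 of the 2-cell list were lower, and none of the biogenesis, splicing, RNA polymerase II and oocyte genes was called in these directions. That fit ended the calls of all 8 genes named as higher (adjusted p = 0.057 to 0.13), of Obox6 (adjusted p = 0.084), and of Kctd12, Glod5, Pramel3 and Olfr815 (adjusted p = 0.053 to 0.059). It also ended those of Rps23, Nop58, Sf3b6, Polr2k and Npm2 (adjusted p = 0.057 to 0.08). AV320801, 10.7-fold lower, was at adjusted p = 0.38 with DESeq2 and adjusted p = 0.17 to 0.2 without siCcnt2 replicate 1, siCcnt2 replicate 2 or siControl replicate 1. The libraries were uneven: siCcnt2 replicate 2 had 13.8% of its counts on mitochondrial genes against 8.72% to 9.1% in the other 3. Fragment length, taken as the median of transcript length minus effective length, was 166.3 bases in siControl replicate 1 against 191.1 to 194.5 in the other 3.

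The change from MII to 1-cell was also compared between poly(A) and total RNA, to ask whether the 2 library types give the same change after fertilisation. Ribosomal protein genes changed upwards in poly(A) relative to total RNA for 50 of 85 and downwards for 4 (52 and 4 adjusted over the list alone): Rps9 changed 15.7-fold more in poly(A) RNA (log2 difference 3.98, SE 0.39, adjusted p = 3.1e-05). The list adjusted p was 5.9e-13, but adjusted p = 0.441 with an estimated correlation. Oxidative phosphorylation genes were relatively higher for 45 of 78 and lower for 3 (51 and 4 adjusted over the list alone). Ndufa8 differed 8.08-fold (list adjusted p = 7.3e-13, but adjusted p = 0.441 with an estimated correlation). Chchd2 rose from 9.4 ± 3.48 to 166 ± 5.42 CPM in poly(A) RNA while total RNA gave 74.2 ± 2.96 and 46.9 ± 4.2 (28.3-fold difference). M phase genes were relatively lower in poly(A) RNA for 15 of 29 and higher for 6 (17 and 6 adjusted over the list alone). Mos differed 4.43-fold (list adjusted p = 0.030, but adjusted p = 0.414 with an estimated correlation). Btg1 and Il1rap fell 9.33- and 6-fold more in poly(A) RNA, Agpat2 rose 35.2-fold more, and Hist2h2aa2 went from no counts to 21.7 ± 4.48 CPM while total RNA gave 232 ± 20.1 and 545 ± 33.9. mt-Co3 moved the other way, with 4 counts in MII total RNA but 714 ± 368 CPM in MII poly(A) RNA.

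This difference was called for 2631 genes higher and 2341 lower of 15571 tested. DESeq2 gave 2066 and 3184 (median from 0.02 to -0.18), RLE factors 2257 and 3136, and library totals 3790 and 249 (median 0.60). Calls dropped from 4972 to 2990 without poly(A) 1-cell replicate 1, to 2881 without replicate 2 and to 3061 without total RNA MII replicate 2.

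Total RNA was compared between consecutive stages to follow the RNA content of each gene. From MII to 1-cell, Duxf3 (ENSMUSG00000075046.7), a Dux homeobox gene, appeared at 10.7 ± 3.54 CPM from no counts, at least 171-fold higher (adjusted p = 6.2e-04), and Mos and March7 fell 14.4- and 14-fold, Btbd1 24.7-fold. Ribosomal protein genes fell for 41 of 87 and none rose (53 lower and 2 higher adjusted over the list alone). Rpl41 fell 4.41-fold to 8.88 ± 1.19 CPM (list adjusted p = 5.1e-30, but adjusted p = 0.189 with an estimated correlation). Oxidative phosphorylation genes fell for 35 of 79 and rose for 1 (49 and 2 adjusted over the list alone). Cox7c fell 9.1-fold (list adjusted p = 6.5e-26, but adjusted p = 0.0946 with an estimated correlation). Mitochondrially encoded proteins rose for 11 of 13, also over the list alone. mt-Cytb rose 2.93-fold to 2970 ± 741 CPM and mt-Nd4l 2.97-fold. Replication-dependent histones rose for 21 of 61 (32 adjusted over the list alone). Hist1h1a rose 1.87-fold to 796 ± 167 CPM. Their list adjusted p-values, 3.6e-12 and 4.0e-11, became adjusted p = 0.189 for each with an estimated correlation. The test called 754 genes higher and 859 lower, 309 and 1205 with library totals, which moved the median from 0.17 to 0, and 130 and 914 in a fit of these 4 libraries alone, which left Hist1h1a at adjusted p = 0.055. The balance turned with DESeq2, 1301 higher and 1109 lower, and without 1-cell replicate 2, 855 and 793. Without MII replicate 1, MII replicate 2 or 1-cell replicate 1 the 1613 calls dropped to 935, 677 and 944, and mt-Co3, which had 4 counts at MII and 45.3 ± 0.11 CPM at 1-cell, lost its call without either MII library. The lists moved too: 27 ribosomal protein genes were lower without MII replicate 1. Without MII replicate 1, MII replicate 2 and 1-cell replicate 1, 19, 21 and 16 oxidative phosphorylation genes were lower. Mitochondrial genes higher were 5 without MII replicate 2, 7 without 1-cell replicate 1 and 7 in the fit of these libraries alone. Histones higher were 9 and 10 without either MII library, 13 without 1-cell replicate 2 and 2 in the fit alone.

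From 1-cell to 2-cell, Tbc1d9 (ENSMUSG00000031709.15) went from no counts to 159 ± 6.78 CPM, at least 1940-fold higher (adjusted p = 3.1e-10), Tdpoz4 at least 856-fold and the transcription factor Gata1 at least 732-fold, while the signalling regulator Rgs2 fell 96.6-fold from 901 ± 92.7 to 9.31 ± 1.44 CPM, Zfp442 133-fold and Pdx1 85.8-fold. Of the oocyte list 25 of 29 fell and 0 rose (27 and 0 adjusted over the list alone). Ooep, of the subcortical maternal complex, fell 41.6-fold from 516 ± 50.3 CPM, and the list call held (adjusted p = 0.0272 with an estimated correlation). The 2-cell transient list rose for 25 of 29 and fell for 2, also over the list alone. Obox6 rose 693-fold to 194 ± 0.66 CPM (list adjusted p = 5.6e-06, but adjusted p = 0.280 with an estimated correlation). Ribosomal protein genes rose for 84 of 87 and fell for 1, with Rpsa 171-fold up to 221 ± 2.92 CPM, and biogenesis genes rose for 32 of 41 and fell for 3, with Nop2 197-fold up to 227 ± 8.72 CPM, the same counts over each list alone. Their list adjusted p-values were 7.2e-29 and 1.1e-11, but adjusted p = 0.230 for each with an estimated correlation. The calls were 5812 higher and 5277 lower of 18390 genes, and RLE factors moved the median of all genes from 0 to -0.18 and turned the balance to 5232 higher and 6118 lower (5086 and 5911 with DESeq2).

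From 2-cell to 4-cell, genes of energy and protein turnover rose. Oxidative phosphorylation genes were higher for 68 of 79 and lower for 0 (70 and 1 adjusted over the list alone). Cox6c rose 17.1-fold to 530 ± 64.2 CPM, and proteasome genes for 34 of 38 with 0 lower (35 and 0 adjusted over the list alone). Psma7 rose 29-fold to 150 ± 3.73 CPM. Both calls held, with adjusted p = 0.0493 for each with an estimated correlation. Among single genes Bc1, a small cytoplasmic RNA, rose 1080-fold to 674 ± 152 CPM, Vnn1 came from no counts (at least 204-fold) and Olfr1423 had 368 counts against 1 (count ratio 377, 95% interval 67.3 to 14900). Hist2h2aa2 fell from 364 ± 11.8 CPM to no counts, at least 3060-fold, while its footprints went the other way, from none to 735 ± 57.8 CPM. The posterior SD of its read assignment was 2.96% of its counts. Whether read assignment produced these opposite swings to and from no counts was not tested. Hist1h2ao fell at least 235-fold and Mfap2 82-fold. Of the 2-cell transient list 15 of 29 fell and 1 rose, also over the list alone. Snai1 fell 9.3-fold (list adjusted p = 0.0073, but adjusted p = 0.411 with an estimated correlation). Calls were 4394 higher and 4920 lower, with the median change moving from -0.09 to -0.32 under library totals.

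From 4-cell to morula, the trophectoderm list (genes of the outer lineage of the blastocyst) rose for 26 of 30 and fell for 1 (26 and 2 adjusted over the list alone): Krt8, a simple epithelial keratin, 163-fold to 636 ± 4.61 CPM and Gata3 216-fold to 199 ± 20.1 CPM. The call held with adjusted p = 0.0064 with an estimated correlation. Primitive endoderm genes rose for 11 of 20 and fell for 2 (13 and 2 adjusted over the list alone). Dab2 rose 13.4-fold and Gata4 fell 29.7-fold (list adjusted p = 2.4e-05, but adjusted p = 0.0639 with an estimated correlation). The 2-cell transient list fell further, 20 of 29 lower and 1 higher (24 and 1 adjusted over the list alone). Obox6 fell 14.5-fold (list adjusted p = 1.9e-05, but adjusted p = 0.211 with an estimated correlation). Plau, Serpinb9b and Serpinb6c came from no counts, at least 308- to 568-fold higher, with Plau at 67.5 ± 7.34 CPM. Ppp1r16b and Obox8 fell 189- and 141-fold, and Hmcn1 to 1 count from 402 (count ratio 545, 95% interval 97.2 to 21600). Calls were 4531 higher and 4505 lower, turning to 4059 and 4964 with DESeq2, and a fit of these 4 libraries alone had 13 of the 2-cell list lower.

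From morula to blastocyst the trophectoderm list rose again, for 22 of 30 with 1 lower, also over the list alone (adjusted p = 0.0035 with an estimated correlation), with Krt8 5.36-fold up to 3410 ± 30.8 CPM and Gata2 125-fold up to 95.6 ± 9.27 CPM. Primitive endoderm genes rose for 13 of 20 and fell for 1 (17 and 1 adjusted over the list alone; adjusted p = 0.0342 with an estimated correlation), with the laminin Lama1 114-fold up to 193 ± 2.98 CPM, and 9 rose without morula replicate 1. Ribosome biogenesis genes fell for 34 of 41 and rose for 1 (38 and 1 adjusted over the list alone). Npm1 fell 3.09-fold to 861 ± 55 CPM (list adjusted p = 3.1e-17, but adjusted p = 0.0603 with an estimated correlation). Flrt3 came from no counts, at least 171-fold, Gulp1 had 747 counts against 2 (count ratio 448, 95% interval 124 to 3710) and Klk7 403 against 1 (count ratio 483, 95% interval 86.3 to 19100). Cphx3, Tmem56 and Barx2 fell 85.6- to 111-fold. Calls were 2141 higher and 2161 lower (2499 and 2374 with DESeq2), 4302 in all, and dropped to 2677 and 2567 without either morula library and to 2549 without blastocyst replicate 1, with 1372 higher and 1177 lower.

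LiRibo-seq was compared between the same stages to follow which mRNAs ribosomes hold, and translation efficiency, the change of footprints minus that of total RNA, to ask where footprints move apart from RNA. From MII to 1-cell, Mos had 912 ± 148 CPM of footprints at MII and none at 1-cell, at least 160-fold lower (adjusted p = 2.7e-04, and 0.068 with DESeq2). Mfn1 (ENSMUSG00000027668.13), which fuses mitochondria, and Mcu, the mitochondrial calcium channel, had none at MII and 751 ± 84.5 and 656 ± 1.53 CPM at 1-cell, at least 868- and 758-fold higher. Dtna rose at least 1870-fold, although its footprints did not follow its RNA later, with 3970 and 4740 CPM in the libraries labelled 2-cell and 4-cell beside 1.04 and 0.395 CPM of total RNA, scaled by library totals alone. Arhgap5 and Leo1 fell at least 105- and 58.1-fold. Footprints of mitochondrially encoded proteins fell for 12 of 13, also over the list alone. mt-Atp6 fell 3.58-fold from 804 ± 126 to 220 ± 37 CPM (list adjusted p = 2.6e-06, but adjusted p = 0.995 with an estimated correlation). Ribosomal protein genes split, 31 of 81 higher and 27 lower (33 and 27 adjusted over the list alone): Rpl27a fell 29.5-fold from 8860 ± 632 CPM, while Rplp0 rose from no counts, at least 133-fold, to 115 ± 1.39 CPM. The list test pointed down relative to other genes (adjusted p = 0.0040, but adjusted p = 0.995 with an estimated correlation), with a median change of 0 and a mean of 0.82. Of 45 ribosomal protein genes above 20 CPM in MII total RNA, scaled by library totals alone, 20 had at most 3 footprints at MII and 16 had over 100 CPM. Calls were 3836 higher and 1093 lower of 8090 genes, and library totals moved the median from 0.81 to 0.17.

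The same transition in translation efficiency asked which maternal mRNAs gain or lose ribosomes beyond the change of their RNA, and its CPM are on the scale of the joint fit. Among genes with much RNA and no footprints at MII, Mfn1 (RNA 311 ± 31.7 and 367 ± 82.8 CPM at MII and 1-cell) reached 506 ± 38.6 CPM of footprints, at least 793-fold, and Ube2g1 (RNA 715 ± 112 and 760 ± 130 CPM), a ubiquitin-conjugating enzyme, 393 ± 20.5 CPM, at least 616-fold. Footprints of Stau1, an RNA-binding protein with 798 ± 5.31 CPM of RNA at MII, rose at least 459-fold, those of the corepressors Sin3b and Mta3 at least 573- and 426-fold, of Mcu at least 694-fold and of Srp54b at least 185-fold. Those of Dtna, with only 9.14 ± 1.4 CPM of RNA at MII, rose at least 1710-fold. Losing all footprints at 1-cell with RNA still present, Arhgap5 fell at least 112-fold, Bbx 44.3-fold and Grpel1 (RNA 80.9 ± 9.69 and 77.9 ± 5.4 CPM) 28.7-fold, and Pogk, Lsg1, Lrguk and Zfp839 at least 21.7- to 32.6-fold. Efficiency of mitochondrially encoded proteins fell for 12 of 13, also over the list alone. mt-Nd4 fell 15.2-fold (list adjusted p = 2.1e-07, but adjusted p = 0.907 with an estimated correlation). Ribosomal proteins had 34 of 81 higher and 24 lower (34 and 25 adjusted over the list alone). Rpl27a fell 23.4-fold. Here too the list test pointed down (adjusted p = 0.013, but adjusted p = 0.965 with an estimated correlation) while the median, 0.75, and the mean, 1.86, were above 0. The test called 3649 of 8036 genes higher and 1051 lower, and the median moved from 0.87 to 1.95 with DESeq2 and to 0.63 with library totals. Among the 2000 most abundant RNAs of MII total RNA 200 had no footprints in both MII libraries, against 13 at 1-cell. The MII LiRibo-seq libraries also differed in fragment length, taken as the median of length minus effective length, at 64.7 and 39.9 bases against 33.7 and 33.8 at 1-cell, and in their share of mitochondrial counts, 1.62% and 0.71% against 0.13% and 0.12%.

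From 1-cell to the libraries labelled 2-cell, footprints of oocyte genes fell for 23 of 26 and rose for 1 (24 and 1 adjusted over the list alone). Zbed3 fell 53.6-fold from 52200 ± 5390 CPM and Btg4, an adaptor of deadenylation, from 4020 ± 192 CPM to none, at least 480-fold (list adjusted p = 1.6e-07, but adjusted p = 0.230 with an estimated correlation). Ribosomal protein genes rose for 77 of 81 and fell for 1, also over the list alone. Rpl4 rose 16.8-fold to 2290 ± 97.8 CPM and Rpl6 from none to 2380 ± 384 CPM, at least 419-fold (list adjusted p = 5.2e-26, but adjusted p = 0.163 with an estimated correlation). Trophectoderm genes rose for 19 of 28 and fell for 2 (20 and 2 adjusted over the list alone). Krt8 rose from none to 1950 ± 82.4 CPM, at least 342-fold (list adjusted p = 7.7e-06, but adjusted p = 0.173 with an estimated correlation). Total RNA of the 2-cell stage had 0.349 CPM of Krt8 when scaled by library totals alone. The 202 late genes, under 1 CPM in total RNA up to the 2-cell stage and at least 20 in a later one, took 1.05% of the footprints in the libraries labelled 2-cell against 0.00589% of 2-cell total RNA, 1.18% of morula footprints and 0.0119% of 1-cell footprints. Their low share of 2-cell total RNA follows from this choice. Poly(A) RNA of siControl 2-cell embryos, which played no part in it, held 0.0452% on these genes. Alppl2 and Calcoco2 came from none (at least 367- and 354-fold), and Obox1 and Pla2g4c fell to none (at least 379- and 372-fold). Calls were 2420 higher and 3225 lower, and library totals moved the median from -0.15 to 0 and turned the balance to 2850 and 2833. A fit of these stages alone called 2408 higher and 3445 lower, with a median of -1.06.

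In translation efficiency the libraries labelled 2-cell differed from 1-cell in the proteasome, with 31 of 34 genes higher and 0 lower (32 and 0 adjusted over the list alone; adjusted p = 0.0103 with an estimated correlation), such as Psmd8 with 65.9-fold. Trophectoderm genes were higher for 19 of 28 and lower for 3, also over the list alone (adjusted p = 0.0103 with an estimated correlation), with Lrp2 384-fold, beside the late-gene share of 1.05% in these libraries. Ribosomal proteins were higher for 58 of 81 and lower for 5 (59 and 5 adjusted over the list alone). Rps4x rose 89.4-fold (list adjusted p = 9.6e-13, but adjusted p = 0.188 with an estimated correlation). Ribosomal protein genes took 8.19% and 8.26% of the footprints in the libraries labelled 2-cell. That compares with 0.87% and 0.86% of 2-cell total RNA and 8.68% and 8.82% of morula footprints. Whether the source of the late-gene footprints also raised the proteasome and ribosomal protein lists was not tested. The decay list was lower for 14 of 25 and higher for 3 (15 and 3 adjusted over the list alone). Footprints of Lsm14b fell at least 160-fold (list adjusted p = 0.0018, but adjusted p = 0.164 with an estimated correlation). Igbp1 had 3.03 ± 0.491 CPM of RNA at 2-cell but 192 ± 13 CPM of footprints from none, at least 50.5-fold higher, and Gata3 2.9 ± 0.0362 CPM of RNA but 265 ± 42.1 CPM of footprints, at least 69.7-fold. Footprints of Fam162a, Fbp2, Psmd10, Rnaset2b, Ube2m and Rfc3 rose at least 16.2- to 65.8-fold. Ice1 (RNA 1630 ± 122 and 1450 ± 64.6 CPM) lost 1030 ± 66.9 CPM of footprints, at least 149-fold, Cdc42se2 at least 144-fold, and Prickle1, Phc2, Ddit4 and Hist1h3i at least 15.3- to 101-fold. Mfsd12 and C2cd2l had only 11 and 12 footprints at 1-cell, at least 1.94- and 2.07-fold above none at 2-cell, while their RNA rose to 42.3 ± 4.15 and 187 ± 1.85 CPM. The calls were 2072 higher and 2718 lower, and the median moved from -0.83 to -0.54 with DESeq2. A fit of these stages alone called 1240 higher and 3974 lower, with a median of -2.11. Of the 2000 most abundant RNAs at the 2-cell stage 409 had no footprints in both libraries.

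**Figure D2:**
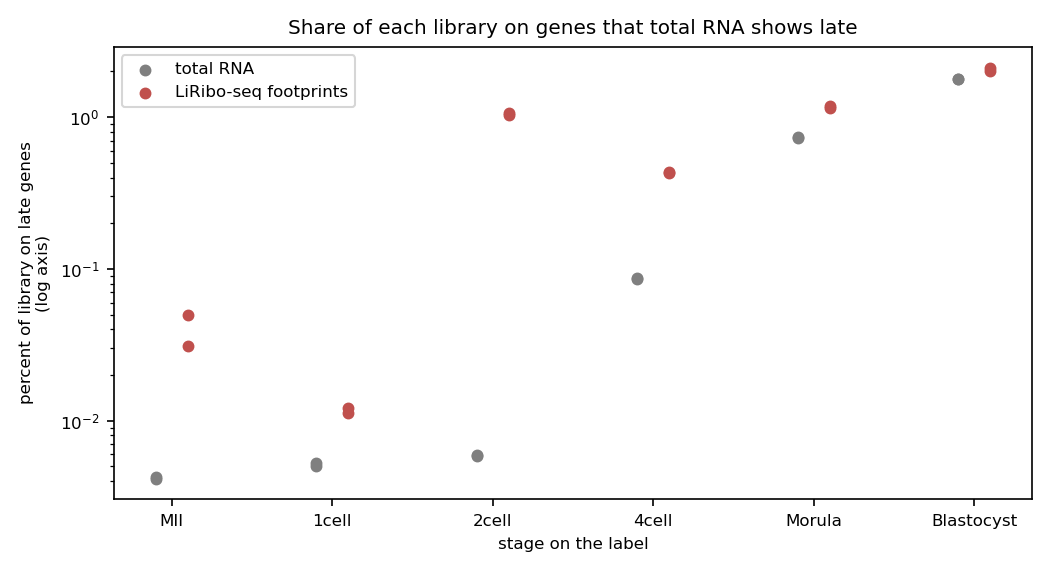
Each point is the percent of a library's counts on the 202 late genes by stage (log axis), in total RNA (grey) and LiRibo-seq (red). At the 2-cell stage the share over both libraries of the group is 1.05% in LiRibo-seq and 0.00589% in total RNA. The low share of total RNA up to the 2-cell stage follows from how the late genes were chosen. Poly(A) RNA of siControl 2-cell embryos, not used in that choice and not shown, held 0.0452%.

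From 2-cell to 4-cell, trophectoderm footprints were lower for 16 of 28 genes and higher for 3, also over the list alone. Cldn4 fell 23.4-fold to 31.3 ± 4.48 CPM (list adjusted p = 0.0043, but adjusted p = 0.162 with an estimated correlation), beside late-gene shares of 1.05% and 0.434% in the libraries labelled 2-cell and 4-cell. Proteasome footprints were lower for 20 of 34 and higher for 2 (20 and 3 adjusted over the list alone). Psmd1 fell 32.1-fold (list adjusted p = 4.6e-04, but adjusted p = 0.835 with an estimated correlation). Hist2h2aa2, the replication helicase gene Mcm6 and Mtf2 came from none, at least 47.6- to 87.7-fold, and Hist1h3b, Calm2 and Tbx20 fell to none, at least 48.2- to 95.6-fold. Calls were 2285 higher and 2157 lower.

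From 4-cell to morula, trophectoderm footprints rose for 19 of 28 and fell for 1, also over the list alone. Krt8 rose 8.83-fold to 2120 ± 40.6 CPM (list adjusted p = 1.8e-04, but adjusted p = 0.256 with an estimated correlation). Proteasome footprints rose for 27 of 34 and fell for 0 (29 and 0 adjusted over the list alone). Psma1 rose 9.24-fold (list adjusted p = 8.7e-06, but adjusted p = 0.529 with an estimated correlation). The pluripotency factor Tfcp2l1 came from none to 699 ± 36.4 CPM, at least 65.4-fold, Hist1h3b and Ezr at least 49.2- and 45.9-fold, and Zbed3, Slc19a3 and Rfpl4 fell to none, at least 568-, 160- and 152-fold. Calls were 3038 higher and 1442 lower, with the median moving from 0.50 to 0.11 under library totals.

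From morula to blastocyst, trophectoderm footprints rose for 21 of 28 and fell for 1, also over the list alone (adjusted p = 0.0236 with an estimated correlation), with the keratin Krt18 3.87-fold up to 4590 ± 138 CPM (adjusted p = 0.077 with the spread of total RNA). Replication-dependent histones rose for 39 of 59 and fell for 1 (44 and 1 adjusted over the list alone; adjusted p = 0.0289 with an estimated correlation), with the linker histone Hist1h1e 3.35-fold up to 1680 ± 102 CPM. Primitive endoderm genes rose for 9 of 16 and fell for 0 (11 and 0 adjusted over the list alone). Lamb1 rose 3.41-fold to 1290 ± 4.12 CPM (list adjusted p = 8.7e-06, but adjusted p = 0.101 with an estimated correlation). Oxct1, Epn3 and Slc15a2 came from none (at least 51.5- to 61.1-fold), and DESeq2 left Epn3 at adjusted p = 0.22 and Slc15a2 at adjusted p = 0.23. Myef2, Hist1h4m and Pbdc1 fell to none, at least 27.5- to 48.4-fold. Calls were 1372 higher and 1123 lower, 2495 in all, and dropped to 920 without morula replicate 2, with 433 higher and 487 lower, and to 1192 and 1403 without either blastocyst library. A fit of these 4 libraries alone called 3990, with 16 primitive endoderm genes higher, and 14 were higher in a fit without the MII libraries. Without morula replicate 2 and blastocyst replicate 1, 22 and 23 histones were higher.

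The later changes of translation efficiency began with the step from 2-cell to 4-cell. Ribosomal proteins were lower for 67 of 81 and higher for 2, also over the list alone. Rpl5 fell 18.9-fold (list adjusted p = 1.7e-29, but adjusted p = 0.0652 with an estimated correlation). Proteasome genes were lower for 32 of 34 and higher for 0 (33 and 0 adjusted over the list alone), and trophectoderm genes lower for 15 of 28 and higher for 2, also over the list alone. Cldn4 fell 415-fold, and both list calls held, with adjusted p = 0.0105 for each with an estimated correlation, beside late-gene shares of 1.05% and 0.434% in the libraries labelled 2-cell and 4-cell. Hist2h2aa2 and Igbp1 changed at least 103-fold up and 18.6-fold down in footprints. From 4-cell to morula, mitochondrially encoded proteins were lower for 8 of 13, also over the list alone. mt-Atp6 fell 5.42-fold (list adjusted p = 4.6e-04, but adjusted p = 0.450 with an estimated correlation). Histones were lower for 32 of 59 and higher for 8 (32 and 9 adjusted over the list alone). Hist1h3c fell 4.13-fold (list adjusted p = 1.6e-06, but adjusted p = 0.290 with an estimated correlation), a median of -1.08 and a mean of 0.46. From morula to blastocyst, ribosomal proteins were higher for 21 of 81 and lower for 1 (25 and 1 adjusted over the list alone). Rpl17 rose 2.54-fold. Histones were higher for 17 of 59 and lower for 3 (20 and 3 adjusted over the list alone). Hist1h2ad rose 8.8-fold. Those list adjusted p-values, 1.7e-10 and 8.3e-06, became adjusted p = 0.362 for each with an estimated correlation. The 3 steps had 2261, 2380 and 889 genes higher and 2156, 1457 and 910 lower. The balance turned with DESeq2 in the step to 4-cell, to 2188 higher and 2307 lower, and in the step to blastocyst, to 1053 and 882. It also turned without LiRibo-seq 2-cell replicate 2 (1780 and 1947), and in the last step without either LiRibo-seq blastocyst library (468 and 465, 641 and 583), either total RNA morula library (745 and 738, 718 and 675) or total RNA blastocyst replicate 2 (756 and 690). The median moved from 0.31 to 0.18 with RLE factors in the step to 4-cell and from 0.77 to 0.23 with DESeq2 in the step to morula. Left-out libraries moved these counts: 3837 became 2365 without LiRibo-seq 4-cell replicate 1, and 1799 became 746 without LiRibo-seq morula replicate 2 and 933 without LiRibo-seq blastocyst replicate 1. Without these last 2 libraries 11 and 9 histones were higher in the step to blastocyst, against 35 in a fit of these stages alone. Ribosomal proteins higher in that step were 63 in the fit alone and 34 without the MII libraries. In the step to morula 5 mitochondrial genes were lower without LiRibo-seq 4-cell replicate 1 or morula replicate 2.

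Ccnt2 and Smarcd2, a subunit of the SWI/SNF chromatin remodeller, are the genes the study's knockdowns target. Ccnt2 lies on chromosome 1 at 127774164 to 127804837 and Smarcd2 (ENSMUSG00000078619.10) on chromosome 11 at 106263171 to 106272998 of GRCm38. Ccnt2 footprints rose 2.22-fold from 261 ± 81.9 CPM at MII to 573 ± 132 at 1-cell (log2 change 1.15, SE 0.27, adjusted p = 0.0015) and fell 7.58-fold to 76.6 ± 5.32 in the libraries labelled 2-cell, whose late-gene share was 1.05% (adjusted p = 2.4e-06), while total RNA gave 195 ± 19, 269 ± 20.5 and 146 ± 0.395 CPM. Its translation efficiency rose 1.52-fold to 1-cell (adjusted p = 0.045) and fell 3.05-fold to 2-cell (adjusted p = 1.9e-04). Smarcd2 footprints were 1 count at MII and 143 counts at 1-cell, 263 ± 32.8 CPM (count ratio 939, 95% interval 166 to 37300, adjusted p = 3.2e-08), with total RNA at 76.7 ± 5.09 and 59.2 ± 11.9 CPM (adjusted p = 0.20), and its translation efficiency rose with adjusted p = 8.9e-12, beside the 200 of 2000 abundant RNAs without footprints at MII. In the same libraries labelled 2-cell Smarcd2 footprints fell 4.62-fold to 63.2 ± 47 CPM (adjusted p = 6.2e-04), and its total RNA at 2-cell rose 2.27-fold to 134 ± 6.64 CPM (adjusted p = 2.2e-05). Poly(A) RNA of Smarcd2 was 1.62-fold lower with CHX (adjusted p = 0.035), and 37.5 ± 2.8 against 31 ± 1.67 CPM with siCcnt2 (adjusted p = 0.45).

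**Figure D3:**
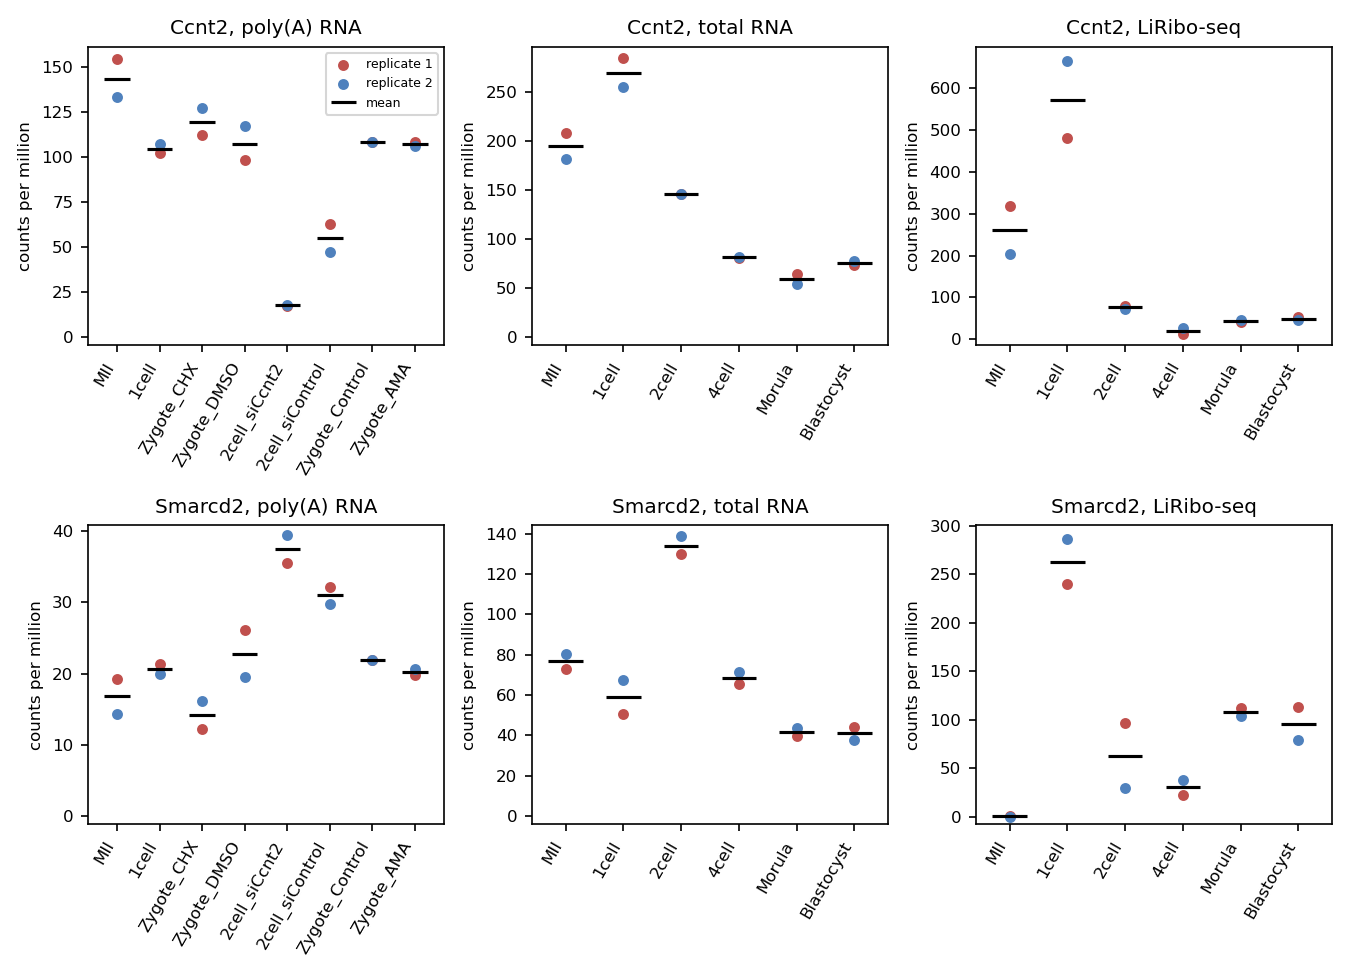
CPM of Ccnt2 and Smarcd2 in every oocyte and embryo group of the 3 assays, with a point per library and a line at the mean. Smarcd2 footprints lie at 0.897 and 0 CPM in the MII libraries and at 240 and 286 CPM at 1-cell.

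The comparisons were also set against each other, in 12 overlaps and 12 correlations of fold changes. Of the 118 genes lower with AMA, 97 were lower with CHX, where 23.8 would be shared at random (Fisher's exact test, two-sided in this paragraph, odds ratio 18.7, 95% interval 11.5 to 31.5, p = 1.7e-47), Usp17lc among them. Of the 2006 genes lower with siCcnt2 and tested in both assays, 1280 rose from 1-cell to 2-cell in total RNA against 650 at random (Fisher's exact test, odds ratio 4.51, 95% interval 4.08 to 4.98, p = 2.8e-209), and 1299 of the 1722 higher ones fell there against 547 at random (odds ratio 8.44). These siCcnt2 calls come from the fit of all poly(A) libraries, whereas the 4 knockdown libraries alone called 4 higher and 116 lower. Every Fisher p here treats genes as independent draws, which genes that move together are not. Of the 3197 genes higher at 1-cell in poly(A) RNA, 2177 were lower with CHX against 646 at random and 106 were lower with AMA against 18.5. Of the 707 genes higher at 1-cell in total RNA, 152 were lower with CHX against 166 at random (Fisher's exact test, odds ratio 0.889, p = 0.22) and 33 lower with AMA against 4.22 (odds ratio 11.7, p = 4.1e-21). The genes higher at 1-cell in poly(A) and in total RNA shared 155 against 126 at random (Fisher's exact test, odds ratio 1.32, p = 0.0041), and the genes lower in both shared 444 against 122 (odds ratio 7.71, p = 1.6e-159). The change from MII to 1-cell correlated at -0.51 with the CHX effect across 20445 genes, and the changes of total RNA and LiRibo-seq at 0.10, 0.46, 0.04, 0.35 and 0.33 in the 5 transitions across 8038 genes, which are not independent replicates.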

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

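All tests of explanations in this part were chosen only after the result was seen, and the bound for α-amanitin was moved from the 10th percentile, which decided nothing, to the lower quartile while both values were known. The test of the difference between CHX and α-amanitin was also added after the data had been seen.

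The change from MII to 1-cell differed between poly(A) and total RNA for 4972 genes, tested as an interaction. The effects of CHX and α-amanitin differed for 4698 genes, 2714 of them more negative and 1984 more positive with CHX, tested as the difference of the 2 contrasts in the poly(A) fit. The ESC LiRibo-seq libraries, which enter no comparison, held 1150.0 CPM of Zfp42, a stem cell marker, against 0 in the MII and 1-cell LiRibo-seq libraries.

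A pattern behind the first of these is the large rise of poly(A) RNA at the 1-cell stage, where 3197 genes rose by a median of 1.99 on the log2 scale. New transcription is unlikely to be its whole cause, since the median change of these genes with α-amanitin was 0.02 and the lower quartile -0.18, although their 10th percentile was -1.78, so part of the genes may depend on it. A larger amount of these RNAs is also unlikely as the whole cause, since their median change in total RNA was 0.15 with a 90th percentile of 1.31. Under TMM, RLE factors, library totals and DESeq2 alike 2973 of the genes were called higher, so the choice among these is not the whole cause. These settings moved the median change of all genes only between 0.178 and 0.656, well below 1.99, so most calls could hardly be lost. All of them scale relative to the library, so a change of the whole poly(A) content after fertilisation was not tested. The median change of the 3197 genes with CHX was -1.86. A longer poly(A) tail on stored RNA that needs new protein is a candidate explanation that stays open, because tail length was not measured here.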

How the results depend on the processing

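The fits of the compared groups alone, with the spread of total RNA, and without the MII or 2-cell libraries were chosen only after the data had been seen, while the other alternatives were planned. No named gene with a call reversed its direction under an alternative, but in 10 of the 20 comparisons the larger of the higher and lower counts changed sides under some alternative. DESeq2, RLE factors or library totals did so in 9 of them, such as poly(A) against total RNA, from 2631 higher and 2341 lower to 2066 and 3184 with DESeq2. Among gene lists the poly(A) median of oocyte genes from MII to 1-cell turned from -0.24 to 0.21 under library totals. Among the named genes and list members, DESeq2 kept the call of 424 and lost 4, RLE factors kept 429, library totals kept 428 and lost 1, no filter kept 428 and gained 1, the replicate block kept 424 and lost 5, and the compared groups alone kept 372, lost 38 and gained 1. Leaving out a library kept 2153 and lost 39 calls, the spread of total RNA kept 75 and lost 1, and the fits without the 2-cell or MII libraries kept all 97 and 139. The α-amanitin count of 119 became 296 without the filter, 78 with a replicate block and 229 with its own 4 libraries alone. With the compared groups alone, siCcnt2 went from 3962 to 120 and total RNA from MII to 1-cell from 1613 to 1044. LiRibo-seq from morula to blastocyst went from 2495 to 3990 and its translation efficiency from 1799 to 2984. In these fits fewer libraries inform both the spread and the scaling factors. Of 169 gene list calls, 20 held with an estimated correlation, which allows for members moving together. With 1 library left out, the poly(A) change from MII to 1-cell (5606) ranged from 3137 to 4455, α-amanitin (119) from 36 to 85, siCcnt2 (3962) from 1820 to 4750, total RNA from MII to 1-cell (1613) from 677 to 1648 and from morula to blastocyst (4302) from 2549 to 2996. LiRibo-seq from morula to blastocyst (2495) ranged from 920 to 1682, translation efficiency from 4-cell to morula (3837) from 2365 to 3818 and from morula to blastocyst (1799) from 746 to 1483, and poly(A) against total RNA (4972) from 2881 to 5331. The libraries that moved these by over 1.5 times were poly(A) MII replicate 2 (3482) and both 1-cell replicates (3615 and 3137), control replicate 1 (57) and both AMA replicates (47 and 36), and siCcnt2 replicate 1 (2351) and siControl replicate 1 (1820). In total RNA they were both MII replicates (935 and 677), 1-cell replicate 1 (944), both morula replicates (2677 and 2567) and blastocyst replicate 1 (2549). In LiRibo-seq they were morula replicate 2 (920) and both blastocyst replicates (1192 and 1403), in translation efficiency 4-cell replicate 1 (2365), morula replicate 2 (746) and blastocyst replicate 1 (933) of LiRibo-seq, and in poly(A) against total RNA both poly(A) 1-cell replicates (2990 and 2881) and total RNA MII replicate 2 (3061). Fits with fewer libraries changed the spread and the scaling factors together, and the cause of these moves was not tested separately. For siCcnt2, scaling alone left 1259 higher and 2702 lower with RLE factors, and 2026 and 1660 with library totals. That argues against scaling as the whole cause of its drop to 120. The siCcnt2 and siControl pairs had a chi-squared per degree of freedom of 106 and 56.9, against 8.06 to 56.8 in the other poly(A) pairs. Equal replicate numbers were checked for pairing: deviations correlated at 0.74 across 7815 genes in total RNA from MII to 1-cell, 0.431 for CHX, -0.357 for α-amanitin and -0.108 for siCcnt2, and genes are not independent replicates. The later steps of total RNA had -0.013 to 0.09. The main fits leave out pairing, and the replicate block of total RNA used the same term for all stages. It therefore does not adjust for a pairing of MII and 1-cell alone. In simulated LiRibo-seq data of the change from MII to 1-cell 10% of 2-fold and 54% of 4-fold changes were found, so genes without a call in that comparison were often not detectable at this depth and number of libraries, which the simulation does not separate.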

Other observations

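All tests of explanations in this part were chosen only after the result was seen, the set of 2-cell genes was redefined from 23 to 107 genes while its values were known, and the pool test at MII and the swap test for the 4-cell stage were added last.

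Other gene groups also moved through the stages in total RNA. Oocyte genes kept falling after the 2-cell stage, with 23 of 29 lower at 4-cell and 23 at morula against 2 higher in each, and 17 lower at blastocyst against 1 higher (adjusted p = 0.0493, 0.0253 and 0.0355 with an estimated correlation). Translation factors rose for 47 and fell for 9 from 2-cell to 4-cell (48 and 9 adjusted over the list alone; list adjusted p = 1.1e-08, but adjusted p = 0.0774 with an estimated correlation). The proteasome list rose for 30 with 0 lower from 4-cell to morula (32 and 0 adjusted over the list alone; adjusted p = 5.0e-10, but adjusted p = 0.0639 with an estimated correlation). SWI/SNF genes fell for 13 and rose for 2 in the same step (14 and 3 adjusted over the list alone; adjusted p = 0.0129, but adjusted p = 0.241 with an estimated correlation). RNA polymerase II and general factors fell for 19 with 0 higher from morula to blastocyst (adjusted p = 0.0342 with an estimated correlation). With siCcnt2, translation factors fell for 23 of 70 and rose for 4 (29 and 4 adjusted over the list alone; adjusted p = 0.034 with an estimated correlation), and the cumulus cell list had no call, nor did it with α-amanitin.

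The ESC libraries held 1090 ± 58.4 CPM of Pou5f1, 682 ± 40.8 of Nanog and 331 ± 10.6 of Sox2, with n = 2. Scaled by library totals alone, Igsf6 had 2270 CPM of footprints at MII, 323 at 1-cell, 1660 and 1620 in the libraries labelled 2-cell and 4-cell, 204 at morula and 251 at blastocyst, but at most 0.191 CPM in the poly(A) and total RNA groups.

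The LiRibo-seq libraries labelled 2-cell held 1.05% of their footprints on late genes that 2-cell total RNA hardly contains (0.00589%). Material from later embryos in these libraries may account for it. The rank correlation of these genes' footprints with the morula libraries was 0.458, with blastocyst 0.371, with 4-cell 0.249 and with ESC 0.216. It cannot decide, because translation of the same genes in 2-cell embryos could also correlate with the later libraries. A swap of whole libraries with the morula or blastocyst stage is unlikely, because 2-cell genes took 0.333% of the footprints against 0.0248% and 0.0202% there. Whether a swap occurred with the 4-cell libraries, which held 0.193% on the same genes, cannot be told from these shares. Late genes took 0.0867% of 4-cell total RNA, but the libraries labelled 4-cell also exceeded that share, with 0.434% of their footprints. A swap as the whole cause is unlikely, since it would leave that 0.434% to explain at the 2-cell stage. Across genes, footprints labelled 2-cell correlated at 0.395 with total RNA of the 2-cell stage, 0.52 with 4-cell and 0.577 with morula, and footprints labelled 4-cell at 0.461, 0.619 and 0.587. Favoured translation of stored RNA also cannot be told apart with these libraries: late genes took 0.0452% of poly(A) RNA in siControl 2-cell embryos, far less than of the footprints, and their low share of total RNA follows from how they were chosen.

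Many abundant RNAs had no footprints in both libraries of a stage, 200 of 2000 at MII, 409 at 2-cell and 163 at 4-cell against 8 to 13 at the other stages. Fewer footprints sequenced are unlikely to be the cause, since thinning the 1-cell, morula and blastocyst libraries to the same depth gave at most 20. At 2-cell and 4-cell 0 of the RNAs at 0 in one library reached 20 counts in its partner, which is consistent with 2 libraries drawn from 1 amplified pool, but RNAs that were truly not translated would give the same, and the 1-cell, morula and blastocyst pairs were as alike with few such RNAs. At MII a shared pool is unlikely, since the chi-squared per degree of freedom between the libraries was 25.04 and 42 RNAs at 0 in one had at least 20 counts in the other. Absence of translation cannot be told apart from loss of footprints at MII, where 20 of 45 ribosomal protein genes had at most 3 footprints and 16 had over 100 CPM.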
